A study of Homo sapiens with 4 samples.

How the data were processed

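RNA from A549 cells was hybridised to 4 arrays, 1 each for untreated cells, cells given 25 μmol/L dihydroberberine, cells given 2 μmol/L sunitinib and cells given both, all at 48 h. Per the labels' protocols, RNA was extracted with TRIZOL, its integrity was read on a Bioanalyzer, it was cleaned on a spin column with DNase, and it was labelled with biotin by a GeneChip 3′ IVT Express kit. The series' design text names an Agilent array instead, and the label field names Cy3. The probe set names and control probes of the values are those of an Affymetrix array, and the values were treated as such. The deposited values are log2 probe set summaries, and Affymetrix Expression Console is named per the submitters' processing notes. Its version, the summarization method and the normalization between arrays are not given in the sources used here. That the deposited scale is log2 was taken from the values, which run from 3.01 to 15.4 with medians between 6.73 and 6.76 on the 4 arrays. Whether the arrays were scaled to each other stays unknown.

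The table held 49395 probe sets, of which 49293 measured genes and 102 were controls. A platform annotation table gave 1 gene symbol for 44988 probe sets and several for 1832, and 2473 were unnamed here. Symbols were compared through the gene identifier with a RefSeq gene table of assembly GRCh38.p14, used for names only, in which 44967 probe sets matched and 0 symbols had to be updated. Each of the 18132 genes was represented by its probe set of highest mean signal over the 4 libraries, so a printed fold is that of this probe set. Genes with at least 1 library at or above a floor were kept, where the floor was the median of all gene probe sets (log2 6.75), which left 10958 genes. Of these, 9831 lay above the floor in all 4 libraries. The floor is not a limit of detection. Background probes with 15 to 25 G or C bases had medians of 6.70, 7.15, 6.99 and 6.95 in untreated, dihydroberberine, sunitinib and combination RNA. Levels just above the floor may therefore be background. Where 1 of the compared libraries lay under the floor, it was raised to the floor and the fold is written as at least that size.

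Groups were taken from the sample titles. With 1 library per group no test was run. Differences of log2 values were counted at a fixed size of 2-fold in each direction, for each drug and the combination against untreated cells and for the combination against each single drug. The deviation from additivity was the combination minus both single drugs plus untreated. The contrasts of 1 drug with and without the other share no library and were set beside each other by Pearson and Spearman correlation across genes and by the number of shared genes, with the product of the list sizes over 10958 as the number for unrelated lists. The number for unrelated lists takes every gene as equally likely to pass 2-fold, which was not tested, so unrelated lists may share more. For overlaps between comparisons that share the untreated library, 100 simulations of unchanged libraries gave the number shared with no effect. Their noise was taken from the additivity deviations, which also hold real effects and are skewed, so it was also drawn with a random sign for each value, a choice made after seeing the data.

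The 26 gene lists were fixed before the data were examined, as were the floor, the 2-fold size and the alternatives except 3. For each list the median log2 difference was given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list under 5 measured genes got no percentile. A percentile below 2.5 or above 97.5 was called outside the central 95%. It describes these libraries only. Of 154 such percentiles 67 lay outside, where 7.7 would by chance if the genes of a list were independent, which co-regulated genes are not.

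Genes were named by a rule fixed in advance. For each drug these were up to 10 higher and 10 lower genes past 2-fold in both contrasts that share no library and above the floor in all libraries. For the combination they were the 10 highest and 10 lowest, with 3 more per direction that had 1 library under the floor. For each drug alone and for the deviation from additivity they were the 5 highest and 5 lowest. For each list they were up to 4 members with the largest difference in the comparison described. All of them needed the same sign in every probe set above the floor, in the comparison that named them. Histone genes are an exception, named after their values were seen.

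The only technical spread that could be computed was that between probe sets of 1 gene on the same arrays. It does not measure the error between libraries, which 1 library per condition leaves unknown. Its median SD was 0.13, 0.13 and 0.12 on the log2 scale for dihydroberberine, sunitinib and the combination against untreated, over 6000 genes with 2 or more probe sets. Of the genes past 2-fold with 2 or more probe sets above the floor, 238 of 277 had the same sign in all of them for dihydroberberine, 34 of 36 for sunitinib and 128 of 136 for the combination. In the combination against dihydroberberine 156 of 205 did, against sunitinib 47 of 48, and for the deviation from additivity 164 of 209. For dihydroberberine, sunitinib and the combination against untreated, the robust SD over all genes was 0.40, 0.27 and 0.37. The median difference of all genes was -0.03, -0.04 and -0.02. Hybridization spikes differed from untreated by medians of 0.06, -0.10 and 0.01, and labelling spikes by -0.23, -0.34 and -0.45. The 3′ minus 5′ signal of ACTB was 0.91, 0.63, 0.85 and 0.82 in untreated, dihydroberberine, sunitinib and combination RNA, and that of GAPDH 0.02, 0.05, 0.04 and 0.04.

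The alternatives were centring each library on its median, quantile normalization of the 4 libraries, no filter, a floor at the 75th percentile, the mean of all probe sets of a gene, raising values under the floor to it, and random lists not matched on expression. Added after seeing the data were the contrast without the dihydroberberine library in place of dihydroberberine against untreated, the contrast without the untreated library in place of sunitinib against untreated, and a count of genes whose probe sets all had 1 sign. The scripts were tested on simulated data with a noise SD of 0.15 and 18132 genes. For dihydroberberine against untreated, 98 of 100 genes with a true log2 size of 1.5 and 100 of 100 with 3.0 passed 2-fold, and 0 of 9202 unchanged genes did. In steps run on the 9402 simulated genes past the filter, 197 of 200 genes changed in both dihydroberberine contrasts were called in both, and 9 of 200 unchanged lists lay outside the central 95%. The changed genes were drawn from bright genes, and the noise of the real libraries is unknown. These rates therefore check the scripts and are not error rates of the real comparisons. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.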

Results

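Gene expression was measured in A549 cells, an established human lung adenocarcinoma line, after 48 h in 4 conditions. The cells were left untreated, received 25 μmol/L dihydroberberine or 2 μmol/L sunitinib, or received both drugs at these doses. Dihydroberberine is a reduced form of the plant alkaloid berberine, and sunitinib is an inhibitor of receptor tyrosine kinases, among them the receptors for VEGF and PDGF. Each condition held 1 array, so the differences between conditions have no replicate check, and the number of arrays limits the precision. The median log2 signal of the gene probe sets lay between 6.73 and 6.76 on the 4 arrays, and the arrays correlated with r between 0.986 and 0.994 across gene probe sets. A total of 10958 genes passed the filter on dim probe sets. Differences are between log2 values of single libraries, and "higher" or "lower" compares those libraries. The difference made by each drug could be read from 2 pairs of libraries with no library in common, alone against untreated and in the combination against the other drug.

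To investigate what dihydroberberine alone did, the library of cells given this drug was compared with the untreated library, and the combination with sunitinib alone. TXNIP, which encodes a thioredoxin-binding protein that restrains glucose uptake, was 21.5-fold lower with dihydroberberine than without, and 14.4-fold lower in the combination than with sunitinib. INSIG1, which holds the sterol sensor SCAP in the endoplasmic reticulum, was 4.36-fold and 2.25-fold lower in these comparisons, and TENT5A, a non-canonical poly(A) polymerase, 3.59-fold and 2.16-fold lower. CCN1, a matricellular protein, was 7.19-fold and 3.5-fold higher, DUSP5, a nuclear phosphatase of ERK, 6.95-fold and 3.39-fold higher, and TIPARP, an ADP-ribosyltransferase induced by the aryl hydrocarbon receptor, 6.02-fold and 3.29-fold higher. Secreted inflammatory proteins were among the higher transcripts as well. CXCL8, a neutrophil chemokine, was 3.3-fold and 5.87-fold higher, PTX3, a long pentraxin, 4.13-fold and 3.29-fold, and IL1A, interleukin 1 alpha, 4.06-fold and 2.79-fold. With sunitinib alone CXCL8 was lower than untreated, with a log2 difference of -1.34, so its 5.87-fold starts from a lower level. NT5E, the cell surface nucleotidase CD73, was 3.72-fold and 3.54-fold higher, and DLC1 3.07-fold and 3.59-fold. GDPD1 was 2.72-fold and 2.80-fold higher, and DAW1, a factor for axonemal dynein assembly, 2.56-fold and 2.83-fold.

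The genes of MAPK feedback and the immediate early response formed the list with the highest median. Of its 23 measured members 17 had a positive difference with dihydroberberine, and the median of 0.78 lay above all 10000 random lists matched on expression. EGR1, a zinc finger factor of the immediate early response, was at least 29.1-fold higher, FOSL1, an AP-1 subunit, 5.49-fold, and DUSP1, a MAPK phosphatase, 3.70-fold. In the combination against sunitinib the median was 0.59, with 21 members positive, again above all random lists. The 16 measured genes of NF-kB and inflammatory cytokines had a median of 0.46, above all random lists, and one of 0.27 (percentile 99.97) in the combination against sunitinib, led by IL1A and CXCL8. The list of epithelial to mesenchymal transition and matrix had a median of 0.23 (percentile 99.9) over 18 genes without sunitinib and 0.06 (percentile 89.8) with it. This list holds both epithelial and mesenchymal genes, so its median gives no direction of the transition. Its members of largest difference were MMP1, an interstitial collagenase, at least 4.34-fold higher, CCN1, and CCN2, another matricellular protein, 2.29-fold higher. The 8 measured targets of the aryl hydrocarbon receptor had a median of 0.29 (percentile 99.2), and one of 0.44 in the combination against sunitinib, above all random lists, with TIPARP and CYP1B1, a cytochrome P450, 6.02-fold and 2.19-fold higher with dihydroberberine alone.

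Genes of lipid synthesis and of cell division were lower. Of 19 measured genes of cholesterol synthesis and uptake, 16 had a negative difference with dihydroberberine alone, and the median of -0.67 had 1 of the 10000 random lists below it. Beside INSIG1, SQLE, the squalene epoxidase, was 2.19-fold lower and HMGCS1, the cytosolic HMG-CoA synthase, 2.04-fold lower. Fatty acid synthesis had a median of -0.68 (percentile 0.01) over 13 genes, where FADS2, a desaturase, was 3.89-fold lower, ELOVL6, an elongase, 2.71-fold, and SCD, the stearoyl-CoA desaturase, 2.11-fold. In the combination against sunitinib these medians were -0.40 and -0.28 (percentiles 0.0 and 0.02). DNA replication genes had medians of -0.50 and -0.35 in the 2 comparisons, below all random lists, with 32 and 35 of 36 members negative. FEN1, the flap endonuclease, was 2.75-fold lower, GINS1, part of the replicative helicase, 2.32-fold, and CCNE2, a G1/S cyclin, at least 1.68-fold. Genes of G2/M and mitosis had medians of -0.40 and -0.26 over 29 members (percentiles 0.06 and 0.0). KIF20A and KIF11, mitotic kinesins, were 2.33-fold and 2.01-fold lower, and FOXM1, a transcription factor of the G2/M genes, 2.14-fold. Cytosolic heat shock genes had medians of -0.31 and -0.14 over 13 members (percentiles 1.44 and 1.28). DNAJA1, a co-chaperone, was 2.31-fold lower and BAG3, another co-chaperone, 2.01-fold lower. Autophagy genes had medians of 0.13 and 0.16 (percentiles 98.6 and 97.8) over 18 members, with OPTN, a receptor for cargo, 1.55-fold higher.

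With dihydroberberine alone 115 genes were at least 2-fold higher and 386 at least 2-fold lower. Of the 115, 43 were also at least 2-fold higher in the combination against sunitinib, where 0.83 would be shared by unrelated lists, and 108 kept a positive sign, with a median of 0.81 against 1.22. Of the 386 lower genes, 6 were at least 2-fold lower in the combination against sunitinib, where 0.46 would be shared, and 285 kept a negative sign, with a median of -0.16 against -1.23. Without the dihydroberberine library, in the combination against sunitinib, a replacement chosen after seeing the data, 79 genes were higher and 13 lower. CUL3, a scaffold of ubiquitin ligases, was 5.74-fold lower with dihydroberberine alone, while its log2 difference in the combination against sunitinib was 0.24. SIK2, a salt-inducible kinase, was 6.88-fold lower alone and 1.58-fold lower in the combination against sunitinib, UNKL, a RING finger protein, 5.02-fold and 1.43-fold, and SETD1B, a histone H3 methyltransferase, 5.00-fold and 1.09-fold. GADD45B, a stress sensor, was 5.19-fold and 1.59-fold higher. Other probe sets gave smaller log2 differences with dihydroberberine alone, down to -0.49 for SIK2, -0.99 for UNKL, -2.62 for TXNIP, 0.82 for FOSL1 and 1.45 for GADD45B. With the mean of all probe sets DLC1, at 0.99, was under 2-fold, and CUL3 had -1.87. On the dihydroberberine array the signal of the Alu control probe set was lower than untreated by a log2 difference of -0.41, and that of the 18S rRNA probe sets by -0.60, whereas the combination array differed by 0.03 and -0.23. Across genes, which are not independent replicates, the 2 differences correlated with a Pearson coefficient of 0.45 and a Spearman coefficient of 0.37. The lower count was 162 with the mean of all probe sets of a gene. With dihydroberberine alone the heat shock and autophagy lists lay inside the central 95% of random lists not matched on expression (percentiles 3.51 and 94.3). In the combination against sunitinib they also lay inside it under an alternative, heat shock after quantile normalization (3.99) and autophagy at the 75th percentile floor (94.6).

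**Figure D1:**
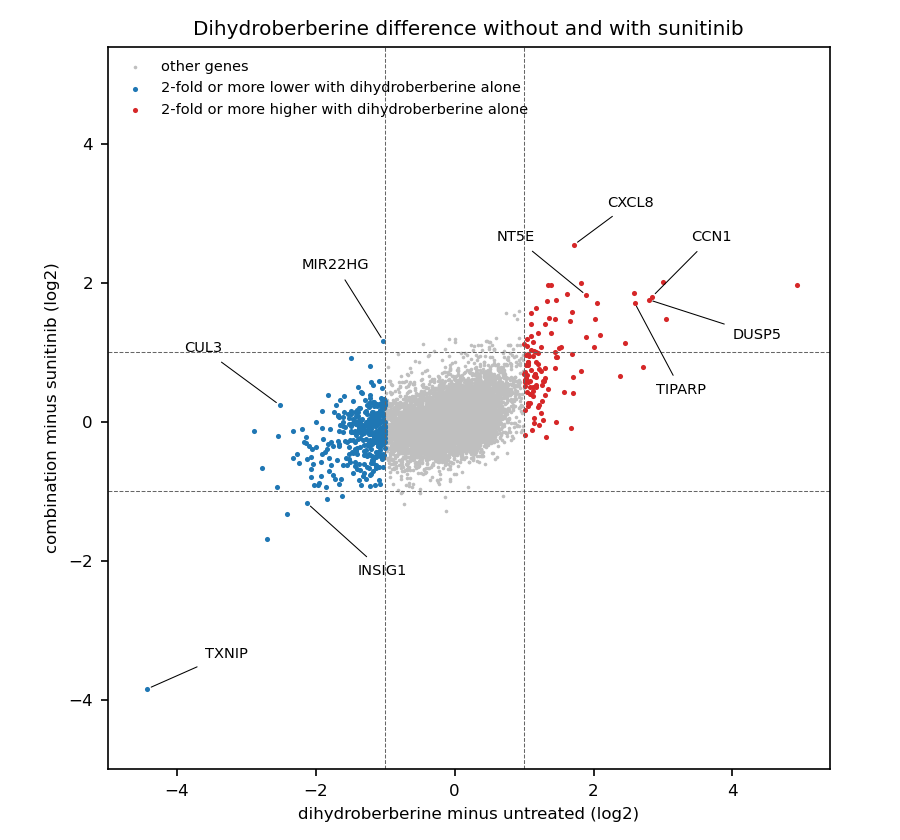
Log2 difference of each of 10958 genes for dihydroberberine against untreated cells (horizontal) and for the combination against sunitinib (vertical). Dashed lines mark 2-fold, and colours mark the 115 genes higher and 386 genes lower with dihydroberberine alone. The red points lie mostly above 0 on both axes, and the blue points spread around a vertical median of -0.16.

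To investigate what sunitinib did, the sunitinib library was compared with the untreated library, and the combination with dihydroberberine alone. IL6, the cytokine interleukin 6, was 2.64-fold lower with sunitinib and 4.09-fold lower in the combination than with dihydroberberine. NRG1, a ligand of ERBB3 and ERBB4, was 2.61-fold and 2.81-fold lower, SUCNR1, the receptor for succinate, 3.02-fold and 2.32-fold, and ANGPTL4, a secreted inhibitor of lipoprotein lipase, 2.30-fold and 2.23-fold. VWA5A was 3.68-fold and 2.65-fold lower, LXN, a carboxypeptidase inhibitor, 2.08-fold and 2.14-fold, and LY6K, a GPI-anchored surface protein, 2.43-fold and 2.08-fold. Fewer genes were higher in both comparisons. SHISA2 was 2.53-fold and 2.26-fold higher, ID2, an inhibitor of basic helix-loop-helix factors, 2.18-fold and 2.44-fold, and BEX2 2.06-fold and 2.27-fold. MEGF6 was 3.53-fold higher with sunitinib. It was 2.3-fold higher in the combination than with dihydroberberine, where its probe sets did not all have the same sign. In sunitinib against untreated cells, NIBAN1, a stress-induced protein, was 3.03-fold higher, FAM13B 2.73-fold and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, 2.41-fold. ARID5B, a chromatin protein, was 3.59-fold lower, PRSS23, a serine protease, 2.97-fold and BMPER, a BMP-binding secreted protein, 2.72-fold. Other probe sets gave smaller log2 differences with sunitinib, down to -0.36 for VWA5A, -0.46 for NRG1, -0.94 for PRSS23, 0.77 for MEGF6 and 0.48 for NIBAN1. With the mean of all probe sets, those under the floor included, SHISA2 at 0.84, FAM13B at 0.92, LY6K at -0.66 and NRG1 at -0.58 were under 2-fold.

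Targets of ATF4 in the amino acid and integrated stress response were higher with sunitinib. Of 28 measured members 23 had a positive difference, and the median of 0.34 lay above all 10000 random lists. NUPR1, a stress-induced chromatin protein, was at least 8.79-fold higher, and WARS1, the cytosolic tryptophanyl-tRNA synthetase, 2.25-fold. The same list had a median of 0.34 with dihydroberberine alone, also above all random lists, where GDF15, a stress-induced cytokine, was 4.26-fold higher and STC2, a secreted glycoprotein, 2.98-fold. Chaperones and degradation factors of the endoplasmic reticulum were lower with sunitinib, at a median of -0.34 below all random lists, with 15 of 18 negative. CALR, a calcium-binding chaperone, was 2.04-fold lower and SDF2L1 1.81-fold. Their median was -0.22 with dihydroberberine alone (percentile 5.04, and 2.12 after quantile normalization). Hypoxia and glycolysis genes had medians of -0.31 with sunitinib and -0.30 with dihydroberberine (percentiles 0.0 and 0.08) over 27 members, which share the untreated library. In the combination against dihydroberberine and against sunitinib, which do not use that library, they were -0.08 and -0.06 (percentiles 7.08 and 6.22). ALDOC, an aldolase, was 2.5-fold lower with sunitinib, and ADM, adrenomedullin, 1.94-fold.

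MAPK feedback and immediate early genes, higher with dihydroberberine, had a median of -0.27 with sunitinib (percentile 0.06) and of -0.45 in the combination against dihydroberberine (percentile 0.0). IER3, an early response gene, was 1.58-fold lower with sunitinib and DUSP5 1.56-fold. In the combination against dihydroberberine EGR1 was 10.7-fold lower, DUSP5 3.20-fold and DUSP1 2.19-fold, while CCND1, cyclin D1, was 2.52-fold higher. Genes of G2/M and mitosis had a median of -0.31 with sunitinib (percentile 0.0), with KIF20A 1.65-fold and AURKB, a mitotic kinase, 1.55-fold lower. DNA replication genes had a median of -0.20 (percentile 0.42), led by CDT1, an origin licensing factor, at 1.66-fold lower. Cholesterol genes had a median of -0.27 (percentile 0.33), with DHCR7, the last enzyme of a cholesterol pathway, 1.51-fold lower, and fatty acid genes of -0.19 (percentile 8.22), with 12 of 13 negative, which was -0.30 (percentile 0.26) with the mean of all probe sets. The interferon response had a median of -0.23 (percentile 0.5) over 14 genes. IRF9, a subunit of the interferon-stimulated factor ISGF3, was 1.66-fold lower and OAS1, an oligoadenylate synthetase, 1.54-fold, while RIGI, an RNA sensor, was at least 1.23-fold higher. With dihydroberberine the interferon median was 0.03 (percentile 52.97). Targets of p53 had a median of 0.13 (percentile 99.3) and those of the aryl hydrocarbon receptor one of 0.24 (percentile 99.9). The 7 drug efflux pumps had a median of 0.36 (percentile 99.98), although ABCG2, a transporter of many drugs, was 1.60-fold lower, and ABCB1, P-glycoprotein, 1.34-fold higher. This median was -0.05 with the mean of all probe sets of a gene. Of 5 measured markers of other cell types, CD14, a monocyte receptor, was at least 4.19-fold lower and CD68, a macrophage protein, 1.77-fold lower with sunitinib, and the median was -0.53 (percentile 0.08). With dihydroberberine CD14 was at least 4.19-fold lower as well, and the median was 0.15 (percentile 68.95).

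In the combination against dihydroberberine, which shares no library with sunitinib against untreated, several of these lists lay inside the central 95%. Targets of ATF4 had a median of -0.005 (percentile 45.5), DNA replication 0.01 (43.5), mitosis -0.07 (8.8), cholesterol 0.03 (50.9), fatty acids 0.17 (87.9), aryl hydrocarbon receptor targets -0.02 (49.3), efflux pumps 0.14 (79.0) and other cell types -0.25 (7.56). Outside it, besides the MAPK list at -0.45 (percentile 0.0) and the p53 targets at 0.27 (percentile 99.04), lay the chaperones of the endoplasmic reticulum at -0.15 (percentile 1.29, and 2.99 after quantile normalization) and the interferon response at -0.22 (percentile 1.78, and 23.8 with no filter). The NF-kB list at -0.28 (percentile 0.03) and that of epithelial to mesenchymal transition at -0.17 (0.77) lay outside as well. With sunitinib against untreated these were -0.02 and -0.08 (percentiles 69.4 and 19.5).

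With sunitinib alone 23 genes were at least 2-fold higher and 64 at least 2-fold lower. The same sign and size was found in the combination against dihydroberberine for 13 of the lower genes and for 5 of the higher genes, SHISA2, ID2, BEX2, MEGF6 and NUPR1, where 0.28 and 0.64 would be shared by unrelated lists. The probe sets of MEGF6 did not all have the same sign in the combination against dihydroberberine. That comparison gave 305 higher and 48 lower genes, and it rests on the dihydroberberine library, whose Alu and 18S signals differed from untreated by -0.41 and -0.60. Across genes the 2 differences correlated with a Pearson coefficient of 0.30 and a Spearman coefficient of 0.27, and with no filter the former was 0.19. The counts with sunitinib alone were 13 higher and 38 lower with the mean of all probe sets, 12 and 37 at the stricter floor, and 14 higher with values raised to the floor, and under each of these settings 7 lower genes were shared. With the mean of all probe sets 3 higher genes were shared, and SHISA2, under 2-fold with sunitinib, was not among them. The DNA replication list with sunitinib lay inside the central 95% of random lists at the stricter floor (percentile 12.4), and so did the MAPK list with the mean of all probe sets (percentile 6.93) and the list of other cell types with no filter (percentile 4.27).

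To investigate what both drugs together did, the combination was compared with the untreated library. SHISA2 was 5.10-fold higher, BEX2 4.87-fold, MEGF6 4.74-fold, TIPARP 4.37-fold and NIBAN1 4.07-fold. NT5E was 3.68-fold higher, IL1A 3.64-fold, GDPD1 3.64-fold, DLC1 3.21-fold and UBASH3B, a phosphatase that acts on receptor signalling, 3.17-fold. Among genes with the untreated library under the floor, NUPR1 was at least 8.30-fold higher, CSTA, the protease inhibitor cystatin A, at least 4.05-fold, and MARCHF4, a membrane ubiquitin ligase, at least 3.80-fold. TXNIP was 9.10-fold lower, SIK2 3.65-fold, TENT5A 3.5-fold, KCNE4, a potassium channel subunit, 3.47-fold and ALDOC 3.44-fold. APOBEC3B, a cytidine deaminase of DNA, had a log2 difference of -1.90, CPS1, the mitochondrial carbamoyl phosphate synthetase, was 3.43-fold lower, NRG1 and INSIG1 3.39-fold each, and FADS2 3.3-fold. With the combination library under the floor, CD14 was at least 4.19-fold lower, NES, the intermediate filament protein nestin, at least 3.32-fold, and TMT1A, a thiol methyltransferase, at least 2.9-fold. Other probe sets gave smaller log2 differences, down to 0.65 for MEGF6, 0.61 for NIBAN1, 1.24 for NT5E, 0.77 for GDPD1, 0.85 for UBASH3B, -0.54 for SIK2, -0.85 for ALDOC, -0.27 for NRG1 and -0.91 for FADS2. With the mean of all probe sets MEGF6 had 1.45, SHISA2 1.38, DLC1 1.07 and NRG1 -0.55, the last under 2-fold.

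Targets of p53 were higher in the combination, with 19 of 21 members positive and a median of 0.34 (percentile 99.97). FAS, a death receptor, was at least 2.12-fold higher, CDKN1A, the inhibitor p21, 2.10-fold, and RRM2B, a subunit of ribonucleotide reductase, 2.04-fold. With dihydroberberine alone the p53 median was -0.01 (percentile 65.8). DNA replication and mitosis had medians of -0.53 each, below all random lists. TK1, thymidine kinase, and CDT1 were both 2.45-fold lower, MCM2, a helicase subunit, 2.15-fold, KIF20A 2.80-fold and AURKA, a spindle kinase, 2.06-fold. Cholesterol genes had a median of -0.62 (percentile 0.0) and fatty acid genes one of -0.43 (percentile 0.09). MAPK feedback genes had a median of 0.42, above all random lists, with FOSL1 2.89-fold and DUSP5 2.17-fold higher. Targets of ATF4 had a median of 0.22 (percentile 99.95), with GDF15 3.1-fold higher. Targets of the aryl hydrocarbon receptor had a median of 0.68, above all random lists, with CYP1B1 2.18-fold higher. Hypoxia and glycolysis genes had a median of -0.34 (percentile 0.0), although NDRG1, a hypoxia-induced gene, was 2.36-fold higher. The chaperones and degradation factors of the endoplasmic reticulum had a median of -0.28 (percentile 0.92), with 14 of 18 negative. CALR was 2.33-fold and SDF2L1 2.31-fold lower, while SEL1L was 1.86-fold and DNAJB9 1.83-fold higher. NF-kB and cytokine genes had a median of 0.09 (percentile 89.0), with IL6 3.08-fold lower and CXCL8 2.32-fold higher. The interferon median was -0.25 (percentile 1.18), with IRF9 1.61-fold lower, and that of the 5 markers of other cell types was -0.73 (percentile 0.07), with CD68 2.14-fold lower. The 36 measured subunits of mitochondrial complex I had a median of -0.20 (percentile 1.485), against -0.16 with dihydroberberine and -0.14 with sunitinib (percentiles 4.53 and 7.42). Autophagy genes had a median of 0.19 (percentile 98.2) and the list of epithelial to mesenchymal transition one of 0.13 (percentile 97.51), with ZEB1, a transcriptional repressor, 2.08-fold higher. The 45 ribosomal protein genes had medians of 0.08, 0.04 and 0.07 with dihydroberberine, sunitinib and both, at percentiles 99.97, 99.8 and 99.6, and in the combination against either drug they were 0.002 and 0.03 (percentiles 74.6 and 87.5). Against random lists not matched on expression, the percentiles with dihydroberberine, sunitinib and both were 93.9, 95.2 and 92.0, inside the central 95%.

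In the combination 127 genes were at least 2-fold higher and 164 at least 2-fold lower than untreated. These held 53 of the 115 genes higher (46.1%) and 61 of the 386 genes lower (15.8%) with dihydroberberine alone, against 1.33 and 5.78 genes for independent lists. In simulations of unchanged libraries against a shared untreated library, 1.56 of 24.0 higher calls and 7.33 of 24.5 lower calls were shared, and 4.95 of 27.4 and 4.57 of 27.0 when the sign of the simulated noise was drawn at random. They held 18 of the 23 genes higher (78.3%) and 39 of the 64 lower (60.9%) with sunitinib alone, against 0.27 and 0.96 genes for independent lists. The simulations shared 1.63 of 23.96 higher calls and 7.45 of 23.4 lower calls, and 5.00 of 27.8 and 4.82 of 27.6 with random signs. Shares of lists of such different lengths cannot be compared, and part of the overlap may come from the shared untreated library. A further 63 higher and 80 lower genes were at least 2-fold from untreated in neither single drug. The higher count was 63 with the mean of all probe sets and 69 at the stricter floor, and the lists of complex I (percentile 5.91 with the mean of probe sets), autophagy (95.3 after quantile normalization), interferon (2.80 against unmatched lists), epithelial to mesenchymal transition (82.8 with the mean of probe sets), other cell types (8.56 with no filter) and ribosomal proteins (89.5 after quantile normalization) each lay inside the central 95% under the named alternative.

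**Figure D2:**
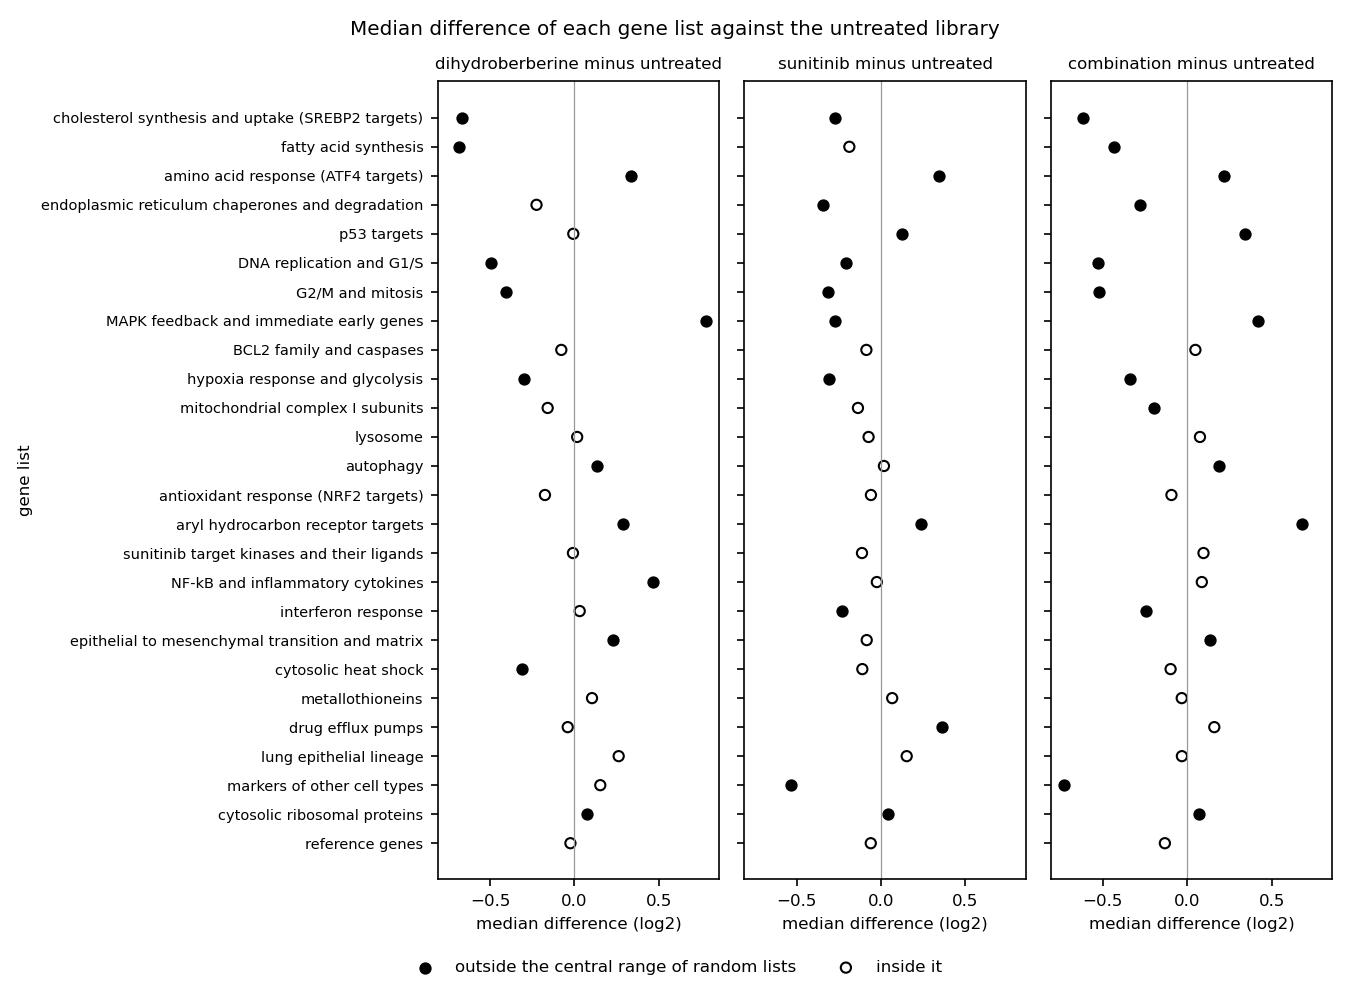
Median log2 difference from the untreated library of each gene list for dihydroberberine, sunitinib and the combination, with 1 library per condition. Filled markers are lists outside the central 95% of 10000 random lists matched on expression. The MAPK list lies at 0.78, -0.27 and 0.42, and the cholesterol list at -0.67, -0.27 and -0.62.

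To investigate whether both drugs together differed from the sum of the single drugs, the deviation from additivity on the log2 scale was taken for the 9831 genes above the floor in all 4 libraries. CUL3 lay 2.76 above the sum, SETD1B 2.2, SIK2 2.12 and HIRA, a histone chaperone, 2.1, and with dihydroberberine alone they were between 4.57-fold and 6.88-fold lower. MIR22HG, the host gene of a microRNA, lay 2.19 above the sum. TSC22D3, a glucocorticoid-induced leucine zipper protein, lay below the sum by a deviation of -1.77, GADD45B by -1.71, PCK2 by -1.53, PRELID3A by -1.46 and FOSL1 by -1.32. PCK2 was 2.48-fold higher with dihydroberberine, 2.41-fold with sunitinib and 2.06-fold with both. The deviation depended on the probe set for SIK2 and HIRA, where others gave values down to 0.13 and 0.42, and others gave -1.11 for TSC22D3 and -0.65 for FOSL1. With the mean of all probe sets CUL3 had 2.04.

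Targets of ATF4 lay below the sum with a median of -0.34, under all random lists, and with medians of -0.005 and -0.03 (percentiles 45.5 and 19.2) the combination stood near each single drug. The MAPK list had a median deviation of -0.26 and the NF-kB list one of -0.32, both below all random lists, and the aryl hydrocarbon receptor list one of -0.22 (percentile 0.27) over 6 genes. The NF-kB median was 0.09 at the stricter floor. Fatty acid genes had a median of 0.35 (percentile 98.1), ribosomal proteins one of -0.04 (percentile 0.08), and 9 lung epithelial genes one of -0.36 (percentile 0.38). With dihydroberberine alone the lung median was 0.26 (percentile 96.2, and 97.6 against unmatched lists). FOXA1, a lung lineage factor, was 2.88-fold lower with dihydroberberine and 2.2-fold lower with both drugs. Targets of p53 were higher in the combination than with either single drug, with medians of 0.27 against dihydroberberine and 0.31 against sunitinib (percentiles 99.04 and 99.99), while their median deviation from additivity of 0.23 (percentile 92.1) lay inside the central 95%. Against dihydroberberine ZMAT3, an RNA-binding p53 target, was 2.65-fold higher and MDM2, the ubiquitin ligase of p53, 2.32-fold, and against sunitinib CDKN1A was 1.74-fold higher. The 5 measured metallothioneins, metal-binding proteins, had a median of -0.34 (percentile 0.28) in the combination against sunitinib.

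At least 2-fold from additivity were 292 genes above the sum and 23 below it, the latter 70 with no filter and 10 at the stricter floor. The dihydroberberine library enters each of these values, and its 386 lower genes contribute to the count above the sum. The count above was 190 after quantile normalization, 96 at the stricter floor and 90 with the mean of all probe sets, and the p53 list against dihydroberberine had percentile 95.9 at the stricter floor. The deviations of the fatty acid list (percentile 96.9 after quantile normalization) and the aryl hydrocarbon receptor list (6.73 with no filter), and the metallothioneins (2.58 with no filter), also lay inside the central 95% under the named alternative.

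In the remaining lists no median of the combination or of the single drugs against untreated lay outside the central 95% of random lists with the values as deposited. Genes of the BCL2 family and caspases had medians of -0.08, -0.09 and 0.05 with dihydroberberine, sunitinib and both, although MCL1, an anti-apoptotic member, was 2.06-fold higher with dihydroberberine and 2.31-fold higher with both, and BIRC2, an inhibitor of apoptosis protein, 2.26-fold higher with both. Lysosomal genes had medians of 0.02, -0.07 and 0.07, with CTSZ, a cathepsin, 2.73-fold lower with both drugs. Targets of NRF2 had medians of -0.17, -0.06 and -0.09, with HMOX1, heme oxygenase, 2.23-fold lower with dihydroberberine. The NRF2 list did lie outside with dihydroberberine after quantile normalization, at -0.16 (percentile 1.33), and with the mean of all probe sets, at -0.24 (percentile 1.24). The kinases bound by sunitinib and their ligands had medians of -0.01, -0.11 and 0.10, with AXL, a receptor kinase, 2.76-fold higher with dihydroberberine and 2.13-fold higher with both. At the stricter floor the kinase list lay outside with dihydroberberine, at -0.63 (percentile 2.33). Reference genes had medians of -0.02, -0.06 and -0.13.

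**Figure D3:**
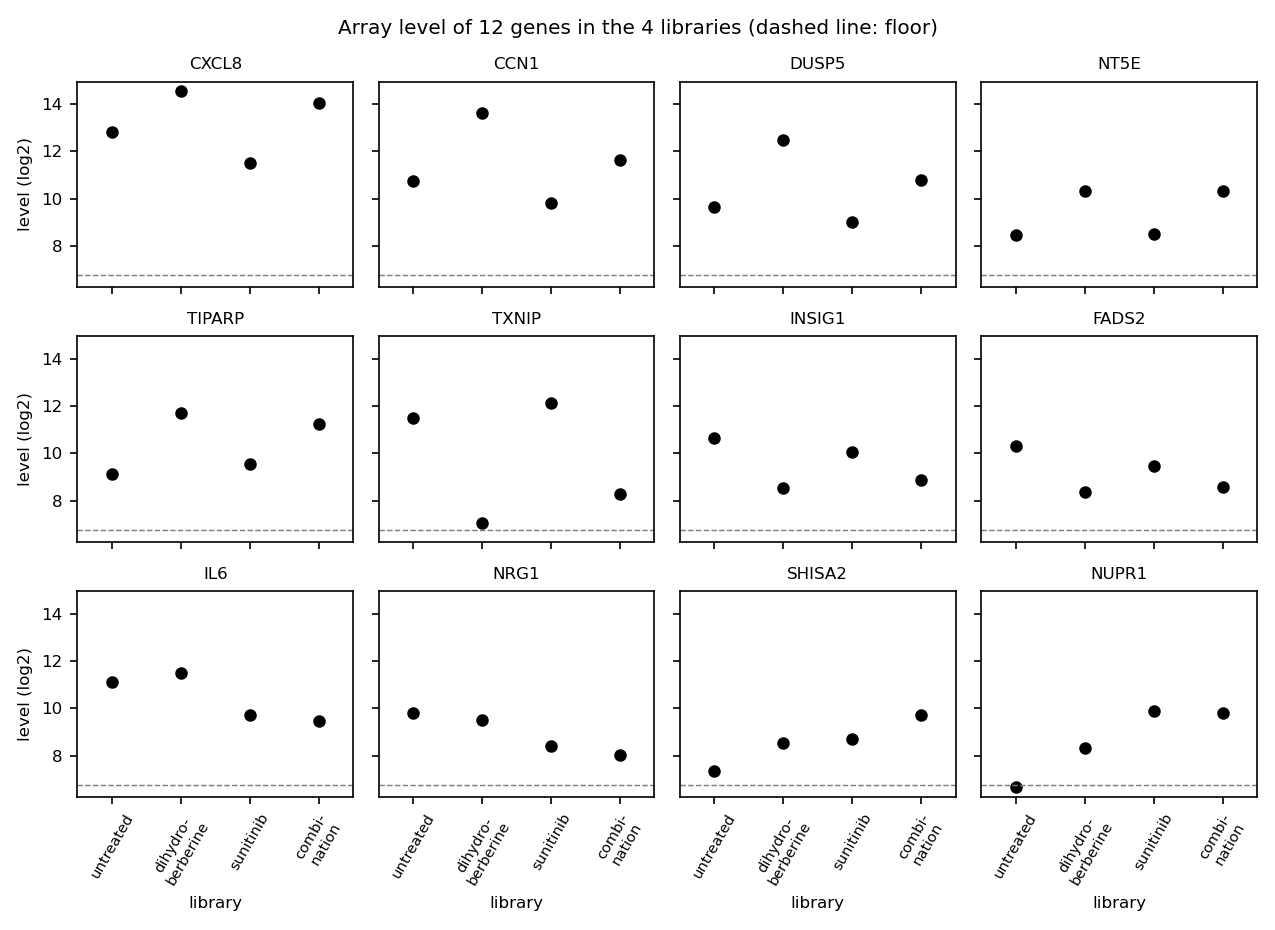
Log2 signal of named genes in the 4 libraries, 1 point per library, with the dashed line at the floor of 6.75. TXNIP lies at 11.5, 7.06, 12.1 and 8.30 in untreated, dihydroberberine, sunitinib and combination cells, and NUPR1 at 6.67, 8.35, 9.89 and 9.81.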

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

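The tests of zinc finger genes and of bright against dim genes were fixed before their results were seen, and the tests of other probe sets, value distributions, handling stress, a response to dihydroberberine and a low untreated library were chosen after. A median over slower MAPK genes, also examined after, was set aside because these genes belong to the list in question.

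MIR22HG was lower with dihydroberberine alone, with a log2 difference of -1.03, and higher when dihydroberberine was given with sunitinib, with 1.17, and the difference between these was not tested. Background probes with 15 to 25 G or C bases, which no comparison used, were brighter than on the untreated array by 0.40 with dihydroberberine, 0.23 with sunitinib and 0.19 with both.

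With dihydroberberine alone 380 genes were at least 2-fold lower that were not so in the combination against sunitinib. Other above-floor probe sets existed for 214 of these genes. Their median was -0.81, against -1.21 for the probe set used, with 201 genes negative and 79 at least 2-fold lower. For these genes this argues against a fault of single probe sets as the cause of the sign, but the 2-fold size depended on the probe set. Genes without another such probe set were not covered. A share of 0.768 of the calls (292) was left after quantile normalization, which argues against the value distributions as the whole cause. The 239 zinc finger genes, whose transcripts are known to be short-lived, had percentile 1.82, past the limit set in advance, but a median of -0.02, so by a rule added after seeing it this decides nothing on short-lived RNA. Against untreated, the same 380 genes had medians of -0.23 with sunitinib alone and -0.41 in the combination. The untreated library enters these values and the selection of the genes, so a high level in that library stays open. The single dihydroberberine library may also differ in its RNA or hybridisation, as its Alu, 18S and background signals do, or sunitinib may offset these effects. None of these was tested, since each condition had 1 library.

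MAPK feedback and immediate early genes were higher with dihydroberberine. Stress during handling of the dihydroberberine culture would not return in another library, but the list was also higher in the combination against sunitinib, a pair without that library, at a median of 0.59 above all random lists. This argues against handling of that culture as the whole cause. The value is consistent with a response to dihydroberberine, as a hypothesis found and examined on the same data. A culture effect common to the 2 libraries with this drug stays open.

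Targets of ATF4 were higher by about the same amount with either drug and with both. Their medians in the combination against dihydroberberine and against sunitinib lay at percentiles 45.5 and 19.24, which is what a low untreated library would give and equally what 2 drugs acting on 1 response would give, and 1 untreated library leaves this open. Array signal near its upper limit would lower the deviation from additivity of bright genes. The 13 brighter genes lay lower than the 13 dimmer ones by a difference of -0.32, past the size set in advance, yet random splits of the same genes differ by up to 0.45 in the central 95%, a spread considered only after the gap was seen. The brighter genes' highest levels had a median of 12.7 against 15.4 for the brightest probe set, so whether a limit of signal contributes stays open.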

How the results depend on the processing

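Alternatives that replace a library or ask for 1 sign in all probe sets were chosen after seeing the data, and the others before. Of 278 values of named genes under alternatives, 246 moved by no more than the robust SD over all genes in that comparison. The other 32 moved further, 28 of these with the mean of all probe sets, and none changed sign. Of 1020 list values 956 kept their side of the limits, and 41 lost and 21 gained a place outside the central 95%. Changes of sign were counted only for medians outside it with the values as deposited. Of these 2 changed sign, the efflux pumps with sunitinib to -0.052 with the mean of probe sets and the NF-kB deviation from additivity to 0.09 at the 75th percentile floor. Of 100 counts 71 stayed within 1.5 times.

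With the mean of all probe sets, genes lower with dihydroberberine numbered 162, genes higher and lower with sunitinib 13 and 38, higher in the combination 63, higher in the combination against dihydroberberine 98, higher and lower against sunitinib 49 and 8, and above additivity 90. Shared by both dihydroberberine contrasts were 28 higher and 3 lower genes, and by both sunitinib contrasts 3 and 7. At the 75th percentile floor, where by construction fewer genes are counted, these were 12 and 37 with sunitinib, 69 higher in the combination, 194 and 30 against dihydroberberine, 52 and 7 against sunitinib, 96 above and 10 below additivity, and 3 and 7 lower in both dihydroberberine and both sunitinib contrasts. With values raised to the floor 14 genes were higher with sunitinib and 7 lower in both sunitinib contrasts. Quantile normalization gave 190 genes above additivity. With no filter 70 genes lay below additivity, and the 2 contrasts correlated with r = 0.32 for dihydroberberine and 0.19 for sunitinib. In place of dihydroberberine against untreated, the combination against sunitinib gave 13 lower genes, and in place of sunitinib against untreated, the combination against dihydroberberine gave 305 higher genes. Except for the stricter floor the cause was not tested. Median centring and the demand for 1 sign moved no count by over 1.5 times. Genes with a library under the floor have only bounds. Other pseudocounts were not run because the values are log2. No paired analysis was possible because the groups share fewer than 2 replicate numbers. An additive fit over the 4 libraries, which would count the deviation from additivity as error, was not run.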

Other observations

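The histone test was chosen after its genes had been seen among the lower ones.

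Histone genes of the replication-dependent clusters, which package newly made DNA, were lower in the combination. Of 19 measured genes 18 had a negative difference from untreated, the median was -0.62, and it lay below all 10000 random lists matched on expression (percentile 0.0). Among the 19, H2AC15 and H4C5 were under the floor in both of these libraries. The median was -0.30 with sunitinib (percentile 0.03) and -0.07 with dihydroberberine (percentile 13.3), and in the combination it was -0.54 against dihydroberberine and -0.39 against sunitinib, both below all random lists. H4C12, a histone H4 gene, had a log2 difference of -1.10 in the combination and H2AC20, a histone H2A gene, one of -1.03. H2BC9, H2AC17 and H1-3 differed by over 1 in the deposited values as well, but with the combination library under the floor, so that these have only a bound. Their untreated levels were 7.28, 7.82 and 7.68 against a floor of 6.75, so the bounds of H2BC9 and H1-3 stay under 2-fold. These 5 genes were chosen after their values were seen. Lower histone transcripts may go with the lower DNA replication genes as a hypothesis. The DNA replication list was lower with dihydroberberine alone too, where the histone list lay inside the central 95%, so the 2 groups were not both lower in every library. Most of these transcripts lack a poly(A) tail, and the labelling primes on poly(A), so the signal may reflect the part that carries one, which was not tested.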
